A study of Mus musculus with 6 samples.

How the data were processed

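Whole-genome bisulfite sequencing (WGBS) reads cytosine methylation at single CpG sites from bisulfite-converted DNA. It was performed on endothelial cells sorted by flow cytometry from mouse placenta. Embryos carried either Dnmt3a flox/flox with the endothelial Cdh5-Cre driver (KO) or Dnmt3a flox/flox without Cre (WT), and were litter-matched per the series description. Each genotype had 3 libraries. Per the labels' protocols, DNA was isolated with a QIAamp DNA Micro kit and libraries were prepared with a Zymo-Seq WGBS kit. The aligner and the methylation caller are not given in the sources used here.

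The authors deposited a table of methylation as a percent per CpG site, with 1 column per library. The values were whole numbers from 0 to 100, and both strands of a CpG shared 1 row. The table listed 20662900 sites after 6 track lines left among its rows were removed, and 19199561 of them (92.9%) had a value in all 6 libraries. No read counts or coverage came with these percents, so the depth behind each site is unknown. No interval or detection limit that needs a depth is given, and the precision of a region rests on its number of CpGs and on the spread between the 3 libraries of a group. The number of sites with a value ranged from 19892527 to 20223853 per library. The share of sites at exactly 100% ranged from 27.6% to 38.3%, and a site read few times reaches 0 or 100 more easily.

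A companion table from the authors lists differentially methylated regions (DMRs) between the genotypes. It holds a p-value and an FDR per region as deposited, a coefficient, a test statistic and an area (each a score deposited by the authors), the width, the number of CpGs and the average methylation difference. The region caller is not given in the sources used here. The deposited difference is a fraction and was multiplied by 100 to give percentage points. The sign of the difference, KO minus WT, was checked against the per-CpG table. The number of CpGs in the table was never above the number of listed sites and equalled it in 290 of 2425 regions. Start and end of all regions lay on listed CpG positions, and region coordinates are given as the table gives them.

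The submitters' processing notes name the build GRCm39. The sites on chromosome 1 run to position 195371431, past the end of that chromosome in GRCm39, and the DMR annotations name mm10, the same assembly as GRCm38. Positions were therefore read as GRCm38. As a check, windows of 1000 bp on each side of the ends of protein-coding genes in the GRCm38.p6 RefSeq gene table held 45.4 CpGs on average with a mean methylation of 57.4%. Windows moved by 20000 bp held 22.1 CpGs with a mean methylation of 79.5%.

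The gene table gives no strand and no exons, and no genome sequence was used here. Promoters were replaced by the CpG-dense gene end, which is the end of each gene with more listed CpGs within 1000 bp on either side. The strand of 939 genes could be taken from the DMR table, and the CpG-dense end was the 5' end in 85.8% of them. It was the 5' end in 94.7% of the 638 genes whose denser end held at least 2-fold more CpGs. The 1475 genes with equal ends were left out. The gene interior is the gene without 1000 bp at either end. Exons and introns were not analysed separately. Mean methylation per library was computed over tiles of 1 kb, CpG-dense gene ends and gene interiors from CpGs with a value in all 6 libraries, and regions needed at least 3 such CpGs.

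The planned main test was a logistic model on methylated and unmethylated reads. It needs read counts, so the fallback stated in the same plan was used, which is limma on the region mean. Limma's moderated test compared 3 KO with 3 WT libraries, with Benjamini-Hochberg adjustment over all regions of a kind. A region was called at an adjusted p under 0.05 and a difference of at least 10 percentage points. On simulated data with the spread of the real libraries, losses of 10, 20, 30 and 50 points were called in 24%, 78%, 98% and 100% of CpG-dense ends. In gene interiors the shares were 40%, 98%, 100% and 98%. In tiles of 1 kb they were 0%, 0%, 18% and 92%, so the tile test missed most moderate losses in this simulation. In each kind of region 50 were changed per size of loss. The adjustment is less strict where more regions change, so the shares in the real data may differ. At a loss of 10 points the 10-point minimum itself removes a part of the changed regions. There were 2 to 3 false calls per simulation. Single values per library were compared by two-sided exact permutation tests, which cannot go below p = 0.1 for 3 against 3 libraries. P-values from limma and the exact permutation tests measure the spread between these libraries, while those for gene lists compare genes with other genes.

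Before the data were examined, 18 gene lists were fixed, covering endothelial subtypes, signalling pathways, developmental and imprinted genes and markers of other cell types. They were tested with limma's camera on log2 of (methylation + 1) over (101 - methylation), with a preset correlation of 0.01 and again with an estimated correlation. In simulated data camera called a list shifted by 0.5 on this scale, and 6 of 100 unshifted lists had an unadjusted p under 0.05. After the data were seen, the share of list members with a deposited lower region in the gene or within 5 kb was compared with 10000 random lists. The random lists were matched in 20 classes of CpG number. The p-value of this permutation rests on the draw of genes and not on the spread between libraries.

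The rule for named genes was fixed before the data were examined. For gene ends and interiors it takes, in each direction, the 10 called genes with a symbol (no Gm, Rik or predicted names) that show the largest difference and whose KO levels all lie on one side of the WT levels. It adds Dnmt3a, all members of the DNA methylation machinery list, and up to 4 called members of every list or, where none is called, the 2 with the smallest p. For deposited regions it takes, in each direction, the 10 with the largest deposited difference that overlap or lie within 5 kb of a gene with a symbol.

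Alternatives covered the minimum difference, the moderation and trend of the variance, the replicate number as a block, each library left out in turn, autosomes alone, centring, the logit scale, the size of windows and tiles, and the number and choice of CpGs. Several were added after the data were seen, among them a covariate for libraries with many or few sites on chromosome Y and a comparison of KO with WT replicate 3 alone. Computations used Python 3.11.15, pandas, numpy and scipy, and R 4.3.3 with limma 3.58.1.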

Results

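The data describe CpG methylation in endothelial cells of the mouse placenta with and without Dnmt3a, which encodes one of the de novo DNA methyltransferases. The series title places the work in the spatial zonation of the placental vasculature. Cdh5-Cre recombines floxed alleles in endothelial cells, and the comparison is between 3 KO libraries (Dnmt3a flox/flox with Cdh5-Cre) and 3 WT libraries (Dnmt3a flox/flox). Values are percent methylation per CpG, with unknown depth. KO replicates 1, 2 and 3 had a value at 19892527, 20215816 and 20073434 CpGs, and WT replicates 1, 2 and 3 at 20223853, 20099491 and 20210071 CpGs. The groups differed in their content of chromosome Y. WT replicates 1 and 2 had a value at 85234 and 80484 of the 104247 listed Y sites, WT replicate 3 at 5659, and the KO libraries at 4145, 5692 and 4861. Comparisons of KO with all WT libraries are therefore also comparisons of libraries with few Y sites with a mixed group. Differences to WT replicate 3 alone are given beside the main counts of gene ends and interiors. They do not test the calls, since 1 library gives no spread of its own.

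The targeted gene was examined first. Dnmt3a lies on chromosome 12 from 3801559 to 3914443, and the floxed part of the gene is not named in the labels. Since the table holds no coverage, listed CpGs without a value were counted along the gene in windows of 1 kb. The window with the largest excess in KO ran from 3902001 to 3903000. In it 6, 2 and 4 of 19 listed CpGs had no value in KO replicates 1, 2 and 3, and all 19 had a value in each WT library. The mean missing share was 21.1% in KO and 0% in WT (n = 3 each, exact permutation test, two-sided, p = 0.1, the smallest possible). The window with the second largest excess in the gene had 20.8 points. An excess as large as in the first was found in 7131 of 1631532 autosomal windows (0.437%), so the window alone does not single out this locus. Of the 1683 listed CpGs of the gene, 7 lacked a value in all 3 KO libraries and in no WT library. Such sites numbered 7103 over all autosomes, and 4287 autosomal sites showed the reverse, among 20662900 listed in the genome. Around the window, 10 CpGs without a value in KO libraries only ran from 3901156 to 3902555. KO-only absence was thus denser in the gene than over the autosomes, which was not tested. Recombination of the gene was not measured otherwise. Methylation over the Dnmt3a interior was 62.2% ± 0.801 in KO and 66.8% ± 0.733 in WT (SD, n = 3 each). This difference of -4.61 points passed limma's test (adjusted p = 0.0170) and lay under the 10-point minimum. At its CpG-dense end the levels were 78.0% ± 2.22 and 76.7% ± 0.936 (limma adjusted p = 0.799). The strand of Dnmt3a was not available, so this end may not be its promoter.

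The first question was whether loss of Dnmt3a lowers the methylation of the genome as a whole. The mean over all CpGs was 74.3% ± 0.175 in KO and 75.6% ± 0.101 in WT (SD, n = 3 each). The difference was -1.29 points, with all 3 KO libraries below all 3 WT libraries (exact permutation test, two-sided, p = 0.1, the smallest possible). All 32 classes of sites examined were lower in KO with no overlap of the libraries, where chance gives complete separation of a single class in 10% of cases in either direction. The classes are overlapping cuts of the same CpGs in the same libraries, so they separate together and do not count as 32 observations. None could pass the threshold, since the smallest adjusted p in this design was 0.1 (exact permutation, Benjamini-Hochberg over 32 classes). Gene interiors had 80.4% ± 0.0452 in WT and 78.7% ± 0.333 in KO, and intergenic CpGs had 79.8% ± 0.0732 and 78.6% ± 0.302. The CpG-dense gene ends had 30% ± 0.184 in WT and 29.1% ± 0.231 in KO, and the less CpG-dense ends 77.6% ± 0.0217 and 75.4% ± 0.384. By level, 1 kb tiles at 20 to 50% methylation showed the largest difference, with 39.7% ± 0.399 in WT and 35.4% ± 0.655 in KO. Tiles at 80% or more had 88.0% ± 0.0272 and 87.1% ± 0.214. Among the autosomes, chromosome 11, which holds the Hoxb cluster, had the largest difference (-1.90 points) and chromosome 3 the smallest (-1.23 points). On chromosome X the KO libraries had 76.4% ± 0.222, WT replicate 3 had 77.1%, and WT replicates 1 and 2 had 78.3% and 78.1%.

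**Figure D1:**
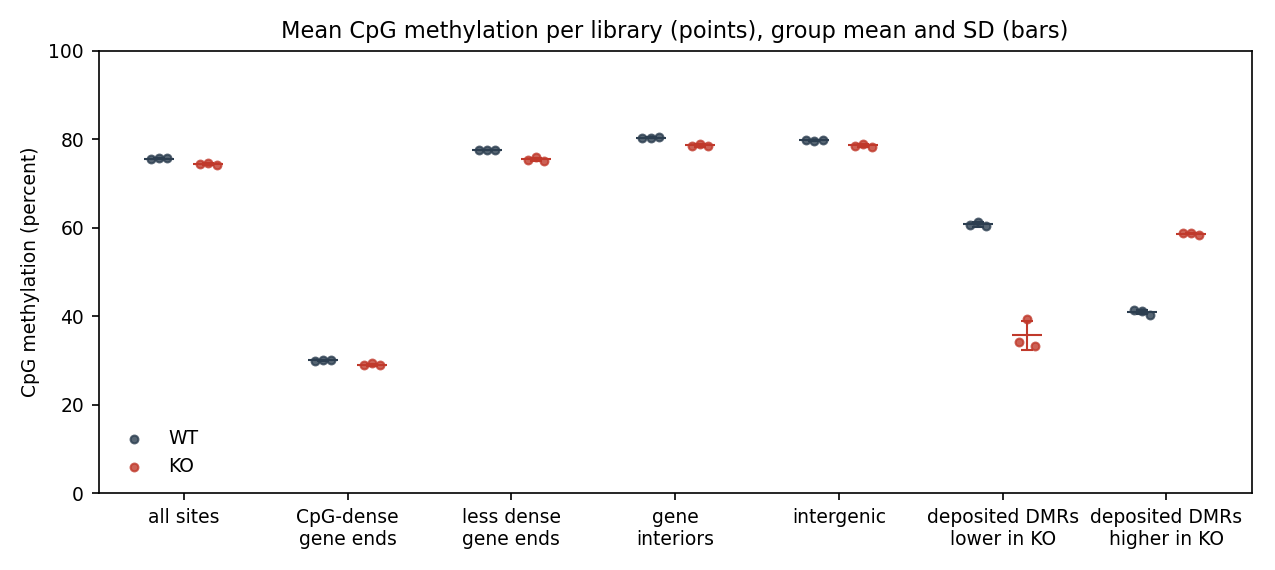
Mean CpG methylation in percent (vertical axis) of the 3 WT and 3 KO libraries over classes of sites and over the regions of the authors' deposited table. Points are libraries, and bars give the group mean and SD. The genome-wide classes shown differ by -0.937 to -2.11 points, while regions deposited as lower in KO lie at 60.8% in WT and 35.7% in KO.

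Tiles of 1 kb were tested to locate differences without reference to genes. Of 2124203 tiles, 0 were called by limma, and 170632 had an unadjusted p under 0.05, of which 76.2% were lower in KO. The smallest adjusted p was 0.0773. With tiles of 5 kb, 1086 of 504853 were called, 1069 of them lower and 17 higher in KO. The called lower 5 kb tiles had a median level of 68.7% in WT and 52.8% in KO, and 64.4% of them held a lower region of the authors' deposited table, against 0.602% of all 5 kb tiles. The 5 kb count was 1, 479 and 2 without KO replicates 1, 2 and 3, and 1, 1 and 9 without WT replicates 1, 2 and 3. It was 0 against WT replicate 3 alone (limma, 32912 at an unadjusted p under 0.05) and 2 with the Y-site class as a covariate. Requiring at least 10 CpGs per 1 kb tile gave 2765 calls, and a variance trend on the number of CpGs gave 3003.

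CpG-dense gene ends stand in for promoters, although some lie at the 3' end of their gene. Of 32778 ends, 72 were called, and all 72 were lower in KO. The largest loss was at Hoxb6, a homeobox gene of the Hoxb cluster, where methylation fell from 67.6% ± 1.77 in WT to 15.6% ± 8.41 in KO (SD, n = 3 each, limma adjusted p = 0.0292). Its 66 CpGs lay on chromosome 11 from 96300569 to 96302569. The end of Irx3os, a long non-coding RNA beside the homeobox gene Irx3, fell from 59.9% ± 3.57 to 11.8% ± 3.75 (limma adjusted p = 0.0121, chromosome 8, 91802336 to 91804336). Pax8, a paired-box transcription factor of thyroid and kidney, fell from 56.8% ± 1.88 to 18.5% ± 1.61 (limma adjusted p = 0.00475, chromosome 2, 24474599 to 24476599). Cldn4, which encodes a tight-junction claudin, fell from 62.1% ± 2.46 to 25.7% ± 3.84. Hoxaas2, a long non-coding RNA of the Hoxa cluster, fell from 61.2% ± 1.89 to 25.5% ± 4.66. The basic helix-loop-helix repressor Hes3 fell from 64.7% ± 2.89 to 29.9% ± 6.20. The T-box gene Tbx4, active in the allantois and hindlimb, fell from 45.0% ± 2.85 to 13.6% ± 4.11. The other 3 of the 10 largest losses were -32.4 points at Bcas3os2, -32.1 at Cercam and -29.3 at Rps6ka4. Among these 10 genes, only Cldn4, Tbx4 and Rps6ka4 had a strand in the DMR table. By this strand the Rps6ka4 end is the 3' end, so this loss is not at its promoter. For the genes without a strand, Hoxb6 among them, the end may not be the promoter. Further called members of the fixed lists were Hoxa7 (-28.3 points), Hoxa6 (-14.4), Hoxd8 (-13.2), the blood and endothelial transcription factor Gata2 (-16.7) and the growth factor gene Tgfb2 (-12.1). The strands of Hoxa6 and Hoxd8 were not available either. The Hoxa6 window also held the end of Hoxa5 at 52204587. The adjusted p of the named calls ranged from 0.00475 to 0.0492 in limma's test.

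These end counts depended on the libraries. With WT replicate 1, KO replicate 1 or KO replicate 3 left out, 0 ends were called, and 1, 46 and 86 were called without WT replicate 2, KO replicate 2 and WT replicate 3. Of the 86 calls without WT replicate 3, 54 were higher in KO. On autosomes alone the same setting called 4 lower and 0 higher ends. Against WT replicate 3 alone all 72 called ends were lower in KO, 71 of them by at least 10 points. Their median difference was -17.49 points to WT replicate 3 and -17.30 to WT replicates 1 and 2. The ends were called with WT replicate 3 in the WT group, which favours this, so these differences are no separate support for the calls. With the Y-site class as a covariate 0 ends were called by limma (2791 at an unadjusted p under 0.05).

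Gene interiors were tested in the same way. Of 28902 interiors, 361 were called, 356 lower and 5 higher in KO, and 4188 lower and 41 higher interiors passed the adjusted p without the 10-point minimum. Of the 361, 4 lay on chromosome X and 1 on chromosome Y, Zfy2, which was lower in KO and is named here after its values were seen. The 10 largest losses again included Hox genes and developmental regulators. Hoxaas2 fell from 80% ± 1.37 in WT to 24.6% ± 3.34 in KO (SD, n = 3 each, limma adjusted p = 0.00462, chromosome 6, 52166675 to 52168450). Hoxa6 fell from 70.3% ± 4.90 to 25.2% ± 3.91 (limma adjusted p = 0.00963, chromosome 6, 52205859 to 52207671). Hoxa11 fell from 38.7% ± 4.24 to 6.32% ± 4.83. The T-box gene Tbx2 fell from 48.8% ± 0.725 to 18.1% ± 5.81 over 235 CpGs. Hand1, a transcription factor of trophoblast giant cells and heart, fell from 61.5% ± 5.72 to 31.7% ± 5.39. Mdk, which encodes the growth factor midkine, fell from 39.3% ± 1.69 to 5.65% ± 5.34. The interior of the stress-inducible gene Gadd45b fell from 35.7% ± 6.76 to 1.19% ± 2.06, over 7 CpGs. The cytokine gene Csf3 fell from 67.8% ± 3.54 to 39.1% ± 7.75, and the losses at Fbxl8 and Commd3 were -36.3 and -28.9 points. The 2 named genes that rose were Triap1 (+13.9 points over 3 CpGs) and Klk1b24, a kallikrein gene (+11.8 points over 7 CpGs). With WT replicate 2 left out 0 interiors were called, without WT replicate 1 11, without KO replicate 1 173 and without KO replicate 3 190. Against WT replicate 3 alone all 361 called interiors kept their direction, 305 of them with at least 10 points. Their median difference was -13.25 points to WT replicate 3 and -13.26 to WT replicates 1 and 2. They were called with WT replicate 3 in the WT group, which favours this, so these differences are no separate support for the calls. With the Y-site class as a covariate 0 interiors were called by limma (5676 at an unadjusted p under 0.05).

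**Figure D2:**
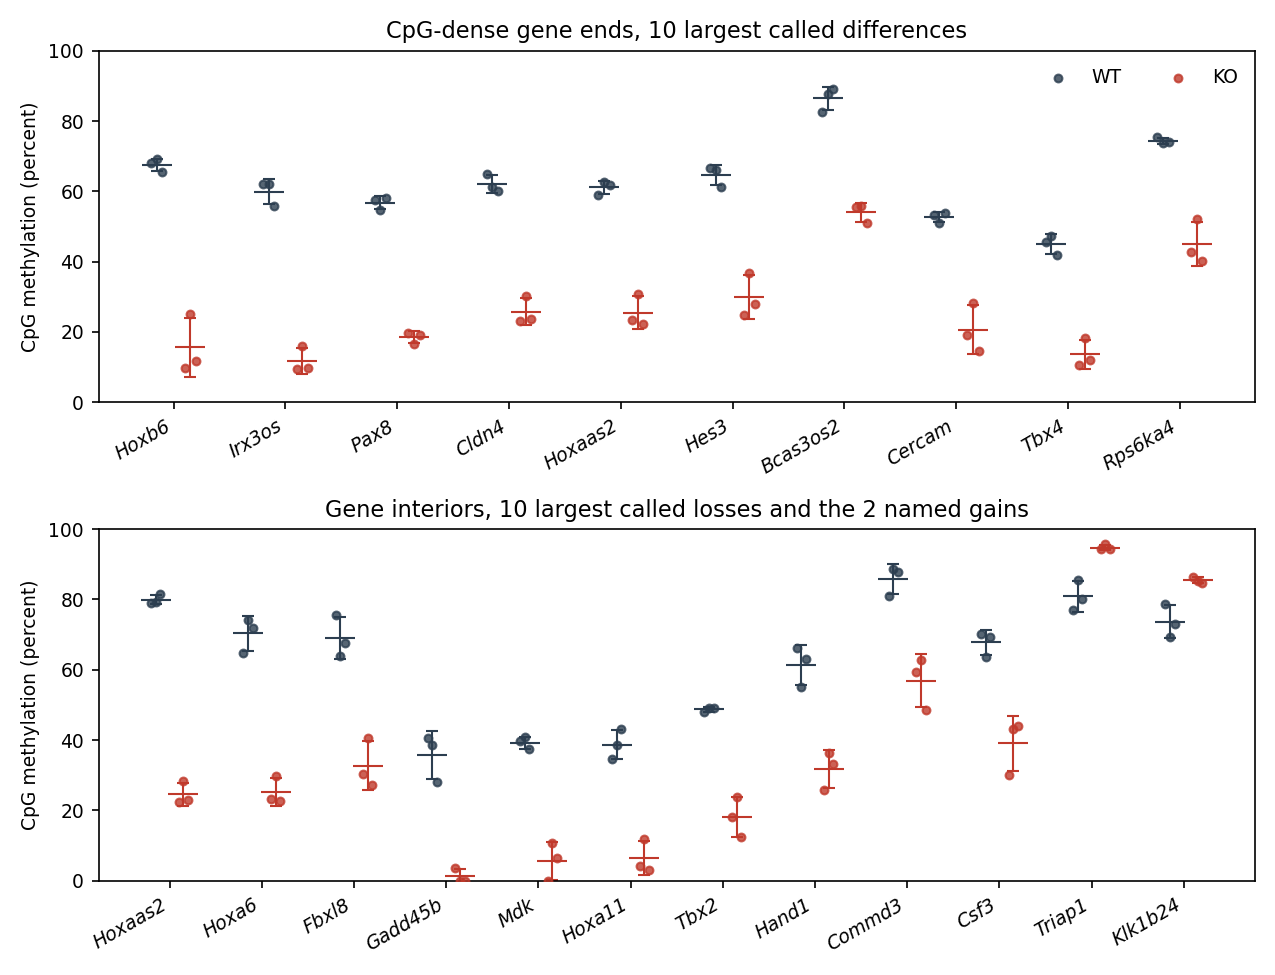
Methylation in percent (vertical axes) at the 10 gene ends and 10 gene interiors with the largest called losses and the 2 interiors with named gains, by gene. Points are the 3 WT and 3 KO libraries, and bars give the group mean and SD. These genes were chosen as called and without overlap of the groups, as Hoxb6 with 15.6% in KO and 67.6% in WT.

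The fixed gene lists were then compared. Over all genes, 78 of 32778 ends and 4229 of 28902 interiors passed limma's test, so a list is expected to hold some passing interiors. Of the 39 Hox genes, 36 had a lower CpG-dense end in KO, 5 passed limma's test over all genes (14 when adjusted over the list alone), and 4 of these were called. Their median difference was -3.62 points, and camera gave an adjusted p = 4.48e-11 (adjusted p = 0.182 with an estimated correlation). In Hox interiors 16 of 34 members passed and 10 were called, among them Hoxd4 (from 68.3% ± 0.379 to 42.0% ± 8.94) and Hoxb3 (from 45.4% ± 1.23 to 20.5% ± 4.37), with a camera adjusted p = 0.00108 (adjusted p = 0.414 with an estimated correlation). Of 88 developmental transcription factors 3 ends were called (6 members passed over the list alone), and 21 of 86 interiors passed, with 8 called, such as Evx1 (-28.2 points) and Isl1 (-16.1 points). Camera did not call this list at ends (adjusted p = 0.596) or interiors (adjusted p = 0.110).

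The endothelial and signalling lists follow. For Notch signalling 11 of 21 interiors passed limma's test, all lower (14 when adjusted over the list alone), and the imprinted Notch ligand gene Dlk1 was called, falling from 50.8% ± 1.87 to 37.1% ± 3.71. The camera adjusted p of this list was 0.00451 in interiors and 0.000643 at ends (adjusted p = 0.414 and adjusted p = 0.182 with an estimated correlation). At ends 0 of its 21 members passed over all genes and 1 passed when adjusted over the list alone. Of 22 arterial genes 8 interiors passed and 0 were called, such as the netrin receptor gene Unc5b (-8.24 points) and Mecom (-5.01), with 11 passing over the list alone. Of 15 venous genes 9 passed (11 over the list alone), such as the prostacyclin synthase gene Ptgis (-6.38 points). Of 18 capillary and angiogenic genes 10 passed (15 over the list alone), and Rgcc fell from 67.0% ± 2.69 to 52.9% ± 2.30. Of 22 pan-endothelial genes 6 passed (9 over the list alone), such as Fli1 (-3.71 points) and Ptprb (-2.50). Camera called the arterial (adjusted p = 0.00419), venous (0.00635) and capillary (0.00243) lists in interiors, and not the pan-endothelial list (0.178). None of these, nor any other interior list, was called with an estimated correlation (smallest adjusted p = 0.414 with an estimated correlation). With the preset correlation camera also called TGF-beta and BMP signalling (0.00395, 8 of 24 members passed, such as Tgfb3 with -6.07 points), Wnt signalling (0.00635, 10 of 25, such as Axin2 with -5.06 points) and nutrient transporters (0.00419, 7 of 22, such as Slc16a3 with -4.85 points). At the CpG-dense ends of these lists 0 members passed limma's test over all genes, except Tgfb2. Adjusted over the list alone, 4 of 19 capillary, 2 of 26 TGF-beta and BMP and 2 of 22 nutrient transporter ends passed, all lower, and 0 of the pan-endothelial, arterial, venous and Wnt ends. The camera adjusted p at ends was 0.844 (pan-endothelial), 0.106 (arterial), 0.939 (venous), 0.0714 (capillary), 0.948 (Wnt), 0.0869 (TGF-beta and BMP) and 0.177 (nutrient transporters).

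The remaining lists were not called by camera, with an adjusted p from 0.0631 (germline ends, direction up) to 0.879 (mesenchymal interiors). Of 18 DNA methylation machinery genes, 0 ends passed limma's test, and 2 interiors passed, Dnmt3a itself and Tet1 (-2.69 points). The interior levels of the other members included Dnmt3b at 81.6% ± 1.36 in KO and 83.5% ± 0.465 in WT and Dnmt1 at 81.1% ± 0.303 and 81.4% ± 0.401. The end of the X-linked gene Mecp2 had 24.0% ± 3.70 in KO, 17.7% in WT replicate 3, and 3.93% and 6.98% in WT replicates 1 and 2 (limma adjusted p = 0.212). Among the markers of cell types that the sort could have included, 0 of 26 trophoblast, 0 of 24 blood and 0 of 22 mesenchymal gene ends passed. In the interiors 5 of 26 trophoblast genes passed, with Hand1 and Gata3 (-10.8 points) called, 1 of 20 blood genes, Coro1a (-7.74 points), and 4 of 22 mesenchymal genes, such as Acta2 (-5.73 points). Of 34 germline genes 0 ends passed, and their median end methylation was 83.2% in KO and 81.6% in WT. In germline interiors 1 of 32 passed, Piwil2 (-2.26 points). Imprinted germline DMR promoters had 0 of 18 ends passing, with Mest at 62.8% ± 4.83 in KO and 77.3% ± 3.41 in WT (limma adjusted p = 0.127), and 1 of 16 interiors, Plagl1 (-3.42 points). Imprinted genes had 0 of 39 ends and 12 of 37 interiors passing, all 12 lower. Cell cycle genes had 0 of 24 ends and 6 of 24 interiors passing, with Cdkn2c, an inhibitor of cyclin-dependent kinases, falling from 28.0% ± 0.502 to 14.9% ± 3.08. Camera compares a list with all other genes, so its direction was up where a list was lowered less than the rest. This was so for the ends of Wnt genes (median -0.588 points) and for the interiors of imprinted germline DMR promoters (median -1.15) and of germline genes (median -0.890).

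The authors' deposited table lists 2425 regions on the 19 autosomes, of which 2403 (99.1%) were lower and 22 higher in KO. The median width was 1267 bp with a median of 17 CpGs, and the FDR in the authors' deposited table ranged from 0.00764 to 0.0499. These regions were chosen on the same 6 libraries, so the levels below describe them and are no independent test. Over the lower regions the recomputed methylation was 60.8% ± 0.530 in WT and 35.7% ± 3.30 in KO (SD, n = 3 each), with KO replicate 2 at 39.4% and KO replicates 1 and 3 at 34.2% and 33.3%. Over the higher regions it was 40.9% ± 0.521 in WT and 58.7% ± 0.179 in KO. The recomputed direction was that of the table in all 2425 regions, and in 2414 of them the 3 KO libraries lay apart from the 3 WT libraries. By the annotation in the authors' deposited table, 63.4% of the lower regions touched introns, 24.7% promoters, 30.4% CpG island shores and 10.4% CpG islands, and 459 of them touched FANTOM enhancers.

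The 10 largest losses at genes with a symbol in the authors' deposited table began with -68.8 points in an intron of Pex14, which encodes a peroxisomal import protein (chromosome 4, 149050237 to 149050989), and -60.6 points in an intron of the homeobox gene Alx4 (chromosome 2, 93644057 to 93645874). A further -60.6 points were listed at an intergenic enhancer within 5 kb of Meis2, a partner of Hox proteins (chromosome 2, 115856913 to 115858498), and -59.5 points at Hoxa3 (chromosome 6, 52177821 to 52179905). The other 6 were Hydin (-58.3 points), the promoter of Sox6 (-57.0), a region within 5 kb of Sall1 (-56.3), the promoter side of Hoxa10 (-56.0), Hoxa5 (-56.0) and the promoter of Hoxa7 (-55.2). The largest gains in the authors' deposited table were 34.4 points within 5 kb of Gipc2 and 34.4 points at the promoter of the channel gene Hcn1. Smaller gains were listed at Zfp993 (29.4), Zbtb7a (28.5), Nek6 (26.5), Dpf1 (24.6), Tgfb1 (23.5), Cadm1 (23.1), Zfp971 (21.0) and Pkd2 (17.3). Recomputed over CpGs with a value in all 6 libraries, the gains at Dpf1, Tgfb1, Zfp971 and Pkd2 were smaller, with 8.33, 8, 15.6 and 3.20 points. At Pkd2 the recomputed mean was 3.56% ± 1.16 in KO and 0.362% ± 0.627 in WT. The 10 named losses were also smaller when recomputed in this way, except near Sall1 (-56.4 points). Pex14 then had -51.3 points and Hoxa10 -45.1, and the region near Meis2 (-57.1) was the largest of the 10. The recomputed values at Hydin and near Sall1 rested on 4 and 5 CpGs.

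All 4 Hox clusters held lower regions and none held a higher one. The Hoxb cluster held 19 and had a mean methylation of 40.8% ± 0.289 in WT and 25.9% ± 2.15 in KO over 3048 CpGs (SD, n = 3 each). The Hoxa cluster held 15, with 23.9% ± 0.498 in WT and 11% ± 1.52 in KO. The Hoxd cluster held 11, with 26.8% ± 0.432 and 15.6% ± 1.32, and the Hoxc cluster 3, with 15.8% ± 0.296 and 12.6% ± 0.416. In each cluster all KO libraries lay below all WT libraries (exact permutation test, two-sided, p = 0.1, the smallest possible).

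**Figure D3:**
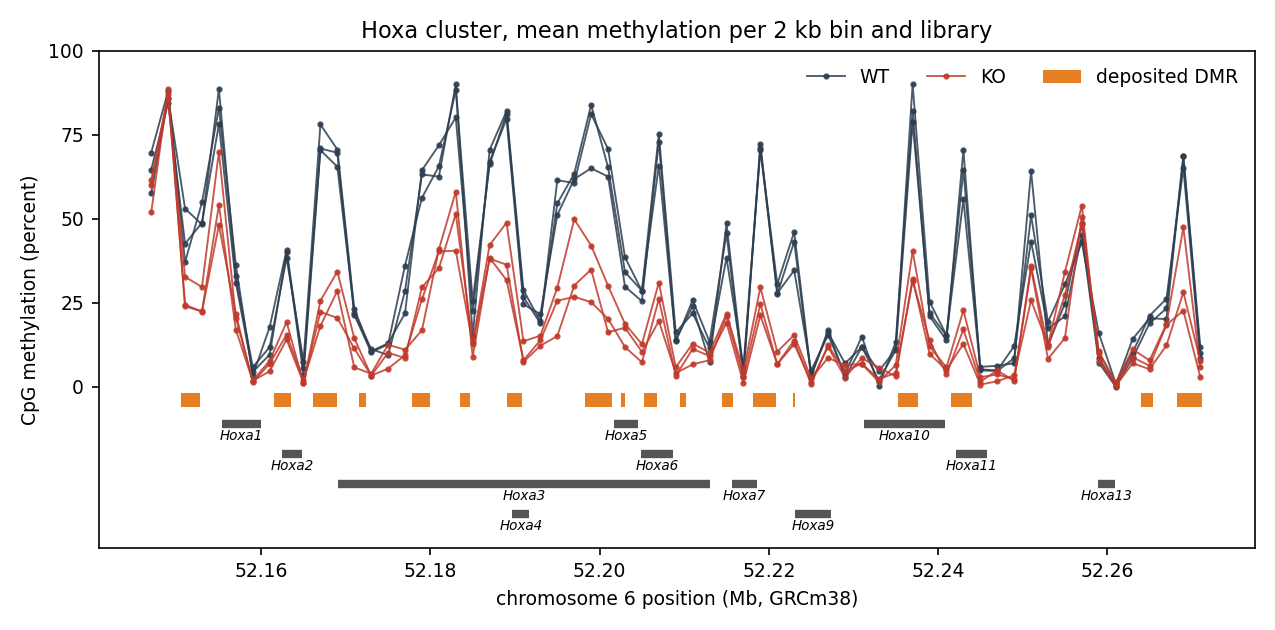
Methylation in percent (vertical axis) along the Hoxa cluster on chromosome 6 (horizontal axis, position in Mb, GRCm38), as the mean per 2 kb bin with at least 5 CpGs. Each line is 1 of the 3 WT or 3 KO libraries, orange blocks are deposited DMRs, and grey bars are Hoxa genes. The KO lines run below the WT lines over most peaks of methylation, and the bins between the peaks vary in level.

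The share of genes with a lower deposited region in the gene or within 5 kb was compared between the fixed lists and random lists with as many CpGs, a test chosen after the data were seen. Of 20502 autosomal protein-coding genes, 6.94% had such a region. Of 39 Hox genes 30 had one, against a mean of 3 in random lists (permutation adjusted p = 0.0009, the smallest the draws can give here). Neighbouring Hox genes share regions, so these members are not independent. Of 88 developmental transcription factors 29 had one, against 8.39 (permutation adjusted p = 0.0009), among them Meis2 (-60.6 points in the authors' deposited table) and Irx3, Tbx1, Gata2, Foxc2 and Meis1, with the largest difference per gene between -51.5 and -44.8 points. Of 21 arterial genes 7 had one, against 1.96 (permutation adjusted p = 0.00945), namely Hey2 (-49.6 points in the authors' deposited table), Unc5b, Ltbp4, Mecom, Jag2, Dll4 and Notch4. Of 16 venous genes 6 had one, against 1.57 (permutation adjusted p = 0.00945), namely Ptgis (-38.5 points), Nr2f2, the main venous transcription factor (-36.8), Nrp2, Vwf, Lrg1 and Flt4. Of 21 Notch genes 7 had one, against 2.27 (permutation adjusted p = 0.0166), and 4 of them (Hey2, Jag2, Dll4 and Notch4) are also in the arterial list. The Notch call was lost when regions had to overlap the gene itself (adjusted p = 0.177) or could lie within 20 kb (adjusted p = 0.0924). The remaining 13 lists did not pass, with 7 of 26 TGF-beta and BMP genes (adjusted p = 0.0627), 5 of 27 trophoblast markers (0.0618), 5 of 22 nutrient transporters (0.0884), 4 of 24 cell cycle genes (0.190) and 4 of 24 pan-endothelial genes (0.288). They also include 4 of 25 Wnt genes, 3 of 22 mesenchymal, 1 of 25 blood, 1 of 19 capillary, 4 of 35 imprinted and 1 of 15 imprinted germline DMR genes, and 0 of 17 machinery and 0 of 32 germline genes.

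**Figure D4:**
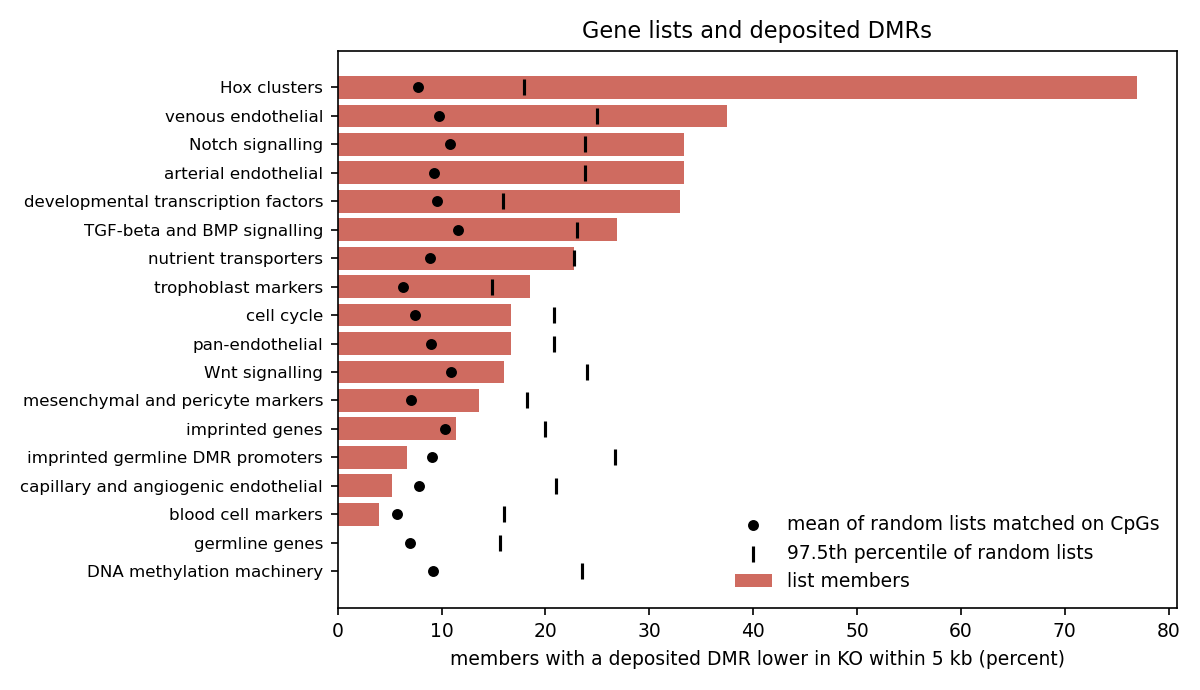
Share of list members, in percent (horizontal axis), with a deposited DMR lower in KO in the gene or within 5 kb, for the 18 fixed lists (vertical axis). Bars are the lists, dots the mean of 10000 random lists matched on the number of CpGs, and ticks the upper end of the central 95% of random lists. The Hox bar reaches 76.9%, and the bars of germline and machinery genes are at 0%.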

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

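The tests of cell admixture, of bisulfite conversion in the deposited regions and in tiles at 80% or more, and of sex in the deposited regions and in regions called without WT replicate 3 were chosen after the values they use had been seen, and the tests of the X-linked gene ends and of conversion in tiles under 80% before. The number of chromosome Y sites with a value was part of no comparison, and it split the WT group. Regions on Y were tested with the rest, and 1 Y-linked interior, Zfy2, was called (49.9% in KO and 72.6% in WT), in libraries that differ in their Y content. WT replicates 1 and 2 had a value at 85234 and 80484 Y sites, against 5659 in WT replicate 3 and 4145 to 5692 in the KO libraries. A candidate explanation is that WT replicates 1 and 2 come mainly from male and the other 4 libraries mainly from female embryos. The labels give no sex.

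X-linked CpG-dense gene ends were higher in KO on average. Over 1121 ends the mean was 57.9% in KO and 52.7% in WT (exact permutation test, two-sided, p = 0.3), with 50% and 49.9% in WT replicates 1 and 2 and 58.2% in WT replicate 3. The difference of KO to WT replicate 3 was -0.289 points and that to WT replicates 1 and 2 was 7.93 points, a ratio of -3.65%. A difference caused by Dnmt3a would have been present against WT replicate 3 as well, and the ratio argues against it for the mean of these ends. A difference in sex between the libraries is consistent with these values. Results on the X chromosome, such as the end of Mecp2, are therefore open to it.

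The deposited regions lower in KO are autosomal, with a mean difference of -25.1 points, and the gap of WT replicate 3 to the KO mean was 97.7% of that of WT replicates 1 and 2, but listing them with this library in the WT group favours such a ratio, so sex and loss of Dnmt3a cannot be told apart by it. Among autosomal interiors called lower without WT replicate 3 the ratio was 87.5% over 76 interiors (above all KO libraries in 74), which argues against sex as the source there, while 4 gene ends (97.0%) and 5 tiles of 5 kb (75.4%) were too few to decide. Incomplete bisulfite conversion adds most where methylation is low, and tiles under 20% differed by 4.73% of the difference in the regions. The regions were listed for a large difference in these libraries, which favours a small share, so this share alone cannot decide. Tiles of 1 kb with 40 or more CpGs were grouped by CpG number and not by difference. They had 14.2% ± 0.259 in WT and 13.7% ± 0.215 in KO, a difference of -0.491 points. If conversion was even over the genome, unconverted cytosines in WT could not give -25.1 points in the regions beside these levels. This argues against incomplete conversion as the whole source of the loss in the regions. Cells of another type in the KO sorts would lower the methylated gene ends of their own markers by about as much as the regions. The median was -2.03 points over 10 trophoblast markers (lowest -13.1 at Lifr) and -1.81 over 17 blood markers (lowest -8.46 at Itga2b). These medians argue against both as the whole source of a loss of that size. In the interiors 5 of 26 trophoblast markers passed limma's test as lower, against 4188 of 28902 interiors over all genes. Hand1 (-29.7 points) and Gata3 (-10.8) were called, so a part from trophoblast cells is not excluded. Only 4 mesenchymal marker ends were methylated in WT (median -3.68 points, lowest -10.7 at Acta2), so admixed mesenchymal cells and loss of Dnmt3a cannot be told apart by this test, and other cell types were not tested.

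In the smaller genome-wide loss, tiles under 20% methylation differed by -1.19 points, 68.3% of the -1.74 points in tiles at 50 to 80%. This lies between the bounds set beforehand for a difference in incomplete bisulfite conversion (at least as large) and for none (less than 50%). Incomplete conversion acts on unmethylated cytosines, so in tiles at 80% or more it would give 13.2% of the difference in tiles under 20%, and the difference there was -0.901 points, or 75.9% of it. This argues against incomplete conversion as the whole source of the genome-wide loss, and does not exclude it for a part of the difference in tiles under 20%. Other conversion errors were not tested.

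Regrouping the 6 libraries into 3 and 3 gives 10 splits, too few for a share under 0.05. Only the real split reached 72 called CpG-dense ends (1 of 10 splits), and the highest of the others gave 1. The real split gave 361 gene interiors (1 of 10), and the highest other 0. For 5 kb tiles the values were 1086 (1 of 10) and 0. For 1 kb tiles the real split gave 0 calls, all 10 of 10 splits gave at least that, and the highest other gave 1, while tiles at an unadjusted p under 0.05 numbered 170632 in the real split and at most 105584 in the others.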

How the results depend on the processing

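The settings with the Y-site class, WT replicate 3 alone, the variance trends, at least 5 or 10 CpGs, all CpGs with a value in each library, the less CpG-dense end, windows of 2 kb at Dnmt3a, the 5 kb tiles with each library left out, and the reach of deposited regions were chosen after the data were seen. The difference in methylation of all CpGs was -1.20 to -1.38 points with each library left out, -1.29 on autosomes and -1.43 over sites with a value in every library. All 32 classes of sites stayed lower without overlap with each library left out, and 31 did with all CpGs of each library. The 2403 lower deposited regions kept their direction with each library left out. The excess of missing values at Dnmt3a was 15.8 to 26.3 points with each library left out and 14.8 in the 2 kb window that holds it. At 2 kb another window of the gene had a larger excess, 19.5 points, so the choice of window did not hold. The CpGs without a value in KO libraries only ran from 3901156 to 3902555, across the start of the first window at 3902001. Of 711 comparisons of the 35 called named genes with an alternative, 429 kept the direction and an adjusted p under 0.05. In 282 the direction was kept without such a p, and 0 reversed. The minimum difference was not applied in this count. Settings that changed only this minimum used the main fit, so they kept the adjusted p by construction. Of 1945 comparisons of 117 other named results, 42 reversed.

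The counts moved more, and unless a reason is given the cause was not tested. The 0 called 1 kb tiles (limma) became 3003 with a variance trend on the number of CpGs, 519 with a trend on the mean level, 641 and 2765 with at least 5 and 10 CpGs, and 1086 for tiles of 5 kb. They were 0 in each other setting, with 78256 to 217445 tiles at an unadjusted p under 0.05 over all settings but the 5 kb tiles. The 72 called CpG-dense ends became 30 at 20 points or more, by construction, 0 without moderation of the variance (3813 at an unadjusted p under 0.05), 24 after centring, 213 and 122 with the variance trends, 40 with all CpGs, 30 on the logit scale, 13 in windows of 500 bp and 218 at the less CpG-dense end. Of the 361 called interiors, 356 were shared with the 361 called on autosomes alone. The count became 4229 with no minimum difference and 65 at 20 points or more, both by construction, 239 without moderation and 176 after centring. With the Y-site class as a covariate both counts were 0 (limma). Against WT replicate 3 alone the called ends and interiors kept their direction, with median differences of -17.49 and -13.25 points. Calling them with this library in the WT group favours this. Both settings leave 1 WT library as the reference for the KO libraries, and this lone library is assumed to vary like the others. With each library left out the counts were 0 to 86 for ends and 0 to 446 for interiors, with 1 library fewer in the test. Of the 72 ends, 27 were shared with the 46 called without KO replicate 2 and 25 with the 86 called without WT replicate 3. Of the called gene lists, 2 for ends and 8 for interiors became 0 and 0 with an estimated correlation. The number of lists with more deposited regions than random lists was 5 with regions that overlap the gene itself and 5 within 20 kb, where Notch signalling was replaced by nutrient transporters and by TGF-beta and BMP signalling.

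The replicate number was also used as a block, although the labels do not say that a number is a litter. Ends, interiors and 5 kb tiles then had 0 calls (limma, 4290, 8320 and 60408 at an unadjusted p under 0.05), with fewer degrees of freedom. Correlations of the residuals of KO and WT libraries with the same number were 0.00780, 0.0218 and 0.0165 at ends. Those with different numbers were all negative there, from -0.0159 to -0.000742. Residuals cancel within each group, so these negative values follow in part from the positive ones and are no further evidence of pairing. In interiors the same-number values were 0.0216, -0.000919 and -0.000184, and the different-number values ran from -0.0283 to 0.0255. The small values go with pairing by number at ends and not in interiors, so pairing stays undecided.

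The reversals were at genes that were not called, with differences under 4 points except at Peg10 (-6.31). After centring the ends of Mbd2 (0.357) and Mbd1 (0.229) and the interiors of Trim28 (0.305), Dnmt1 (0.944), Dnmt3l (1.19), Uhrf1 (0.636) and Hells (0.564) were higher in KO, since centring removes the loss shared by all regions. With the Y-site class, and equally against WT replicate 3 alone, the ends of Mbd4 (-0.0598), Mbd3 (-0.632), Tdg (1.26) and Mbd2 (0.231) and the interior of Zfp57 (-0.111) reversed. With all CpGs the end of Uhrf2 (0.0951) and the interior of Uhrf1 (0.239) did. In windows of 500 bp the ends of Zfp57 (0.0833), Uhrf1 (0.187), Mbd2 (0.563), Mbd1 (0.938), Uhrf2 (0.208) and Peg10 (6.04) did. With each library left out the ranges at ends were -2.36 to 0.382 (Uhrf2), -0.297 to 0.430 (Mbd3), -0.413 to 0.254 (Mbd2), -0.990 to 0.331 (Mbd1), -0.0705 to 0.571 (Mbd4), -0.187 to 0.0747 (Trim28) and -1.94 to 5.15 (Dnmt3l). For interiors they were -0.382 to 0.855 (Zfp57) and -0.716 to 0.0657 (Dnmt3l).

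Since the table holds no read counts, the following settings, chosen before the data were examined, were not run: read minimums of 5 and 20, removal of CpGs with over 5 times the mean coverage, the count model, coverage-weighted levels or levels from CpGs with at least 5 reads, deposited regions with at least 10 reads, and coverage of Dnmt3a against its flanks. Depth limits the precision of each percent to an unknown degree.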

Other observations

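Apart from limma's test of interiors, no test in this part was planned before the data were examined. Some gene lists held no deposited region. None of the 17 autosomal machinery genes and none of the 32 autosomal germline genes measured had a lower deposited region in the gene or within 5 kb, where random lists with as many CpGs held 1.57 and 2.22 on average. Whether this is fewer than chance gives was not tested. Interiors of Dnmt3a, Tet1 and Piwil2 in these lists passed limma's test as lower all the same. Among imprinted genes the lower deposited regions were at Kcnq1 (-30.3 points in the authors' deposited table), Dlk1 (-27.2), Cdkn1c (-21.3) and Mest (-18.0). Among transporters they were at Fcgrt, the neonatal Fc receptor gene (-35.3 points), the monocarboxylate transporter gene Slc16a3 (-32.6), the glucose transporter gene Slc2a3 (-28.9), Slc27a1 (-27.8) and Lrp1 (-21.2). The cell cycle inhibitors Cdkn2c (-38.2) and Cdkn2a (-30) and the cyclin gene Ccnd2 (-26.4) also had one. The Tgfb1 gene held a higher region, with 23.5 points (8 points recomputed over CpGs with a value in all 6 libraries), and 2 lower regions were listed within 5 kb of it, the larger with -27.0 points.

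The KO libraries were not alike in the lower regions. KO replicate 2 had 39.4%, against 34.2% and 33.3% in KO replicates 1 and 3. It also had the smallest number of Dnmt3a CpGs without a value in the window from 3902001 to 3903000, with 2 of 19, and the smallest number in the whole gene among the KO libraries, with 80 of 1683 against 145 and 199. The WT libraries had 31, 108 and 71, so its count lies within their range, and it also had the most CpGs with a value of the KO libraries, 20215816. The share of recombined cells was not measured, and 3 libraries do not allow a test of this relation.

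Of the 22 higher regions, 12 (54.5%) were annotated as intergenic and 5 (22.7%) as CpG island in the authors' deposited table, against 26.7% and 10.4% of the lower regions, and this difference was not tested. CpGs of the mitochondrial genome had a mean of 26.5% to 30.6% in the KO and 29.4% to 30.7% in the WT libraries, over 244 to 253 sites. Whether these values reflect methylation or cytosines left unconverted was not tested.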
